A study of Homo sapiens with 8 samples.

How the data were processed

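Total RNA of 4 human cell lines was sequenced after depletion of ribosomal RNA, with 2 libraries per line. The lines were U937 (leukemic), EaHy (endothelial), PC3M (prostate cancer) and HEK293 (embryonic kidney). The authors trimmed the reads with cutadapt, aligned them to the human genome build hg19 with TopHat2 2.0.11 and estimated expression with Cufflinks 2.2.1, and the deposited values are FPKM per gene symbol, with a single column per library. No further normalization between libraries is stated in the labels. Counts were not used, so no counting intervals or detection floors are given, and a gene listed at 0 is described as such without a fold change when both HEK293 libraries are at 0.

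FPKM were analysed as log2(FPKM + 0.5) in R 4.3.3 with limma 3.58.1. Genes with at least 0.5 FPKM in at least 2 of the 8 libraries were tested, 16295 of 23615. A linear model with a term per cell line was fitted, with the variance prior allowed to follow the expression level, and U937, EaHy and PC3M were each compared with HEK293. Two-sided p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was called. With 2 libraries per line, the adjusted p-values come from this model fitted across all genes, and they measure the spread between libraries collected in duplicate. The differences between replicates correlated across lines at −0.15 to 0.33, the highest for U937 with HEK293, so the replicate numbers were not taken as pairs, and a replicate block was run as an alternative. Genes called in the same direction in the 3 comparisons were counted. Since the comparisons share the HEK293 libraries, the counts were set against 50 simulated data sets without changes.

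The binding class was not tested as a factor, since it sets 3 lines against 1. A GPCR was counted as shared by the binding lines and missing from HEK293 when it had at least 0.5 FPKM in each of the 6 libraries of the binding lines and less in both HEK293 libraries. The list held 357 GPCRs.

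A total of 29 gene lists were written before the data were examined: all GPCRs, lipid and oxylipin GPCRs, arachidonate and EET metabolism, fatty acid nuclear receptors and binding proteins, G protein signalling, monocyte and myeloid, lymphoid, endothelial, epithelial, prostate, neuronal and embryonic kidney, matrix, integrin and adhesion, NF-κB and inflammatory, interferon-stimulated, MHC, immediate early, HOX, cholesterol synthesis, hypoxia, stress, proliferation, ribosomal protein, replication histone, abundant noncoding RNA, blood stem and progenitor, and housekeeping genes, besides 2 lists whose results are not given. The 27 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over all lists and comparisons. Called members were counted after adjustment over all genes and after adjustment over the list alone.

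The rule for the genes named in the text was also written before the data were examined. It took each GPCR that met the presence rule and GPR132 with its receptor family. Per comparison it took the 8 called genes with the largest increases and the 8 with the largest decreases, and for the 3 comparisons together 10 in each direction by the smallest of the 3 changes, leaving out small RNA and unnamed loci by their symbols. Per list and comparison it took up to 4 called members with the largest changes, or 2 members with the highest mean FPKM where none was called. It gave 255 genes, of which the text names a part. Genes named outside it were chosen after their values were seen: LPAR6, AGTR1 and NPY1R, the genes listed at 0 in all libraries, and those so described in the closing section. Genes of X inactivation and Y-linked genes were not named.

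Alternatives were other pseudocounts, other filters on low values, upper-quartile scaling, quantile normalization, a single prior spread, a robust prior, a replicate block, a test against a fold of at least 2, fits with only the lines compared, and leaving out each library in turn, where a lone library is assumed to vary like the other lines. A call lost without a library can therefore come from the larger standard error with an unchanged fold change. A term for the 3 histone-rich libraries, a rescaling without small RNA and histone genes, a fit of the histone-poor libraries, and a presence rule for a single library per line were chosen after the data were seen. Recovery of added changes was tested on simulated data built from these values: at a log2 change of 1, 0% of 50 changed genes were recovered in each comparison, at 2 between 6% and 10%, at 4 between 68% and 74%, and at 6 between 92% and 98%. In the same simulated data, 5, 15 and 12 genes without an added change were called in U937, EaHy and PC3M. The gene annotation used for neighbours and transcript lengths was of another build than the deposited values, and no positions are printed.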

Results

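RNA sequencing after depletion of ribosomal RNA was used to look for G protein-coupled receptors (GPCRs) that bind epoxyeicosatrienoic acids (EETs), epoxide products of arachidonic acid. Libraries came from 3 lines with EET binding, the leukemic line U937, the endothelial line EaHy and the prostate cancer line PC3M, and from the embryonic kidney line HEK293, which lacked it. Each of the 4 lines gave 2 libraries from cells collected in duplicate, 8 libraries in all, so p-values describe the spread between these libraries. The binding class set 3 lines against a single line, and HEK293 was also grown in another medium than the other lines. Length-normalized expression values (FPKM) were listed for 23615 gene symbols, of which 16295 were tested. The sum of FPKM per library was 627041 and 625638 in U937, 497389 and 1926028 in EaHy, 1337962 and 1490477 in PC3M, and 647103 and 612905 in HEK293. No read counts were used here, so the depth in counts is unknown.

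The libraries of EaHy replicate 2, PC3M replicate 1 and PC3M replicate 2 stood apart from the other 5. RMRP, the RNA of a nuclear and mitochondrial ribonuclease, stood at 276000, 476000 and 507000 FPKM in these 3 libraries, and between 12.3 and 1130 FPKM in the other 5. The median of 42 replication histone genes, as log2(FPKM + 0.5), was 8.05, 9.83 and 8.49 in them, against 3.14 and 0.82 in U937, 1.91 in EaHy replicate 1, and 2.98 and 1.21 in HEK293. Small RNA genes made up 83.6%, 65.2% and 81.8% of all FPKM in the 3 libraries and 18.5% to 53.3% in the other 5. Across the 16295 tested genes, which are not independent replicates, EaHy replicate 2 correlated with PC3M replicate 1 at r = 0.83 and with EaHy replicate 1 at r = 0.78. The other pairs of replicates correlated at r = 0.874 in U937, 0.843 in PC3M and 0.92 in HEK293. Both PC3M libraries belonged to the 3, so each PC3M difference from HEK293 below went along with this library difference.

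**Figure D1:**
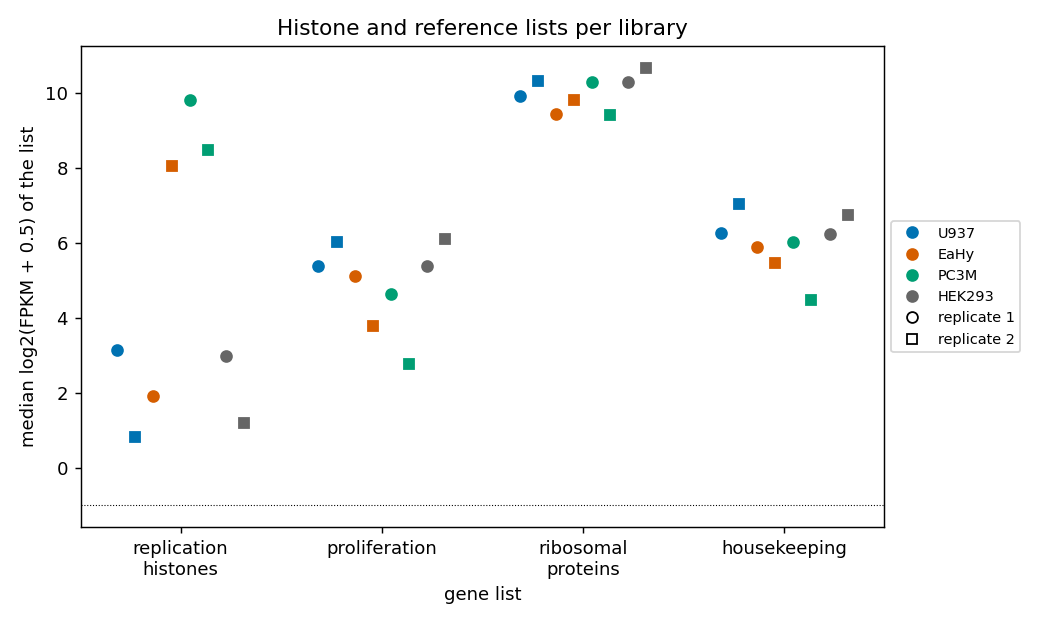
Median log2(FPKM + 0.5) of 4 gene lists (vertical axis) in each of the 8 libraries, with circles for replicate 1, squares for replicate 2 and colors for the lines. The histone medians of EaHy replicate 2 (8.05), PC3M replicate 1 (9.83) and PC3M replicate 2 (8.49) lie above those of the other 5 libraries, and the dotted line marks a gene listed at 0.

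A total of 863 genes were listed at 0 in all 8 libraries. Among them were HLA-B, a classical MHC class I gene, and the ubiquitously used genes CSNK2B, BRD2, RPS18, TUBB and DAXX. The receptor genes GABBR1, CRHR1 and MAS1L were listed at 0 as well, so their presence could not be judged. B2M, the light chain of MHC class I, was listed at 81.1 to 1180 FPKM.

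The U937, EaHy and HEK293 libraries were highest for the marker lists of their lines, while the prostate list was not higher in PC3M. Of 49 tested monocyte and myeloid genes, 47 were higher in U937 than in the mean of the other 3 lines, with a median log2 difference of 5.25. Of 33 tested endothelial genes, 28 were higher in EaHy (median 4.67), and of 27 neuronal and embryonic kidney genes, 18 were higher in HEK293 (median 2.66). Of 32 epithelial genes, 10 were higher in PC3M and 2 lower (median 0.81). Of 10 tested genes of the prostate list, 1 was higher in PC3M and 2 lower (median −0.76). The median of the prostate list was 0.44 in HEK293. Of 41 listed matrix genes, 32 were tested and 20 of these were higher in EaHy than in the other lines (median 3.10).

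**Figure D2:**
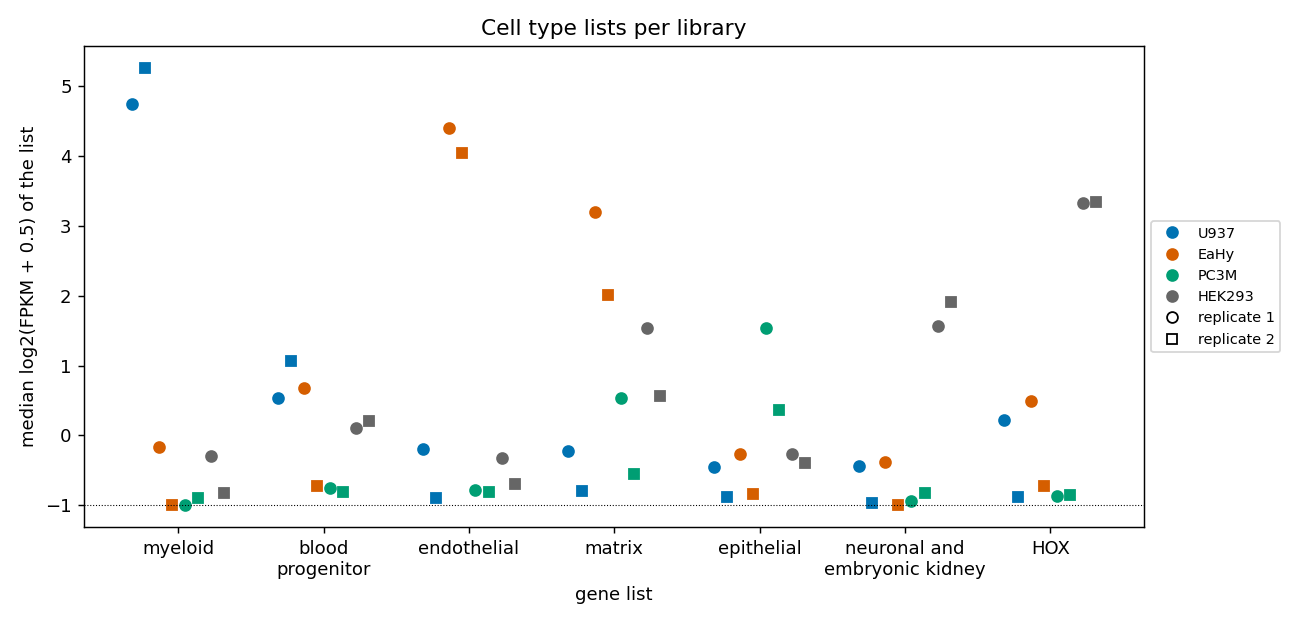
Median log2(FPKM + 0.5) of 7 gene lists (vertical axis) in each of the 8 libraries, with circles for replicate 1, squares for replicate 2 and colors for the lines. The myeloid medians of U937 (4.74 and 5.26) and the endothelial medians of EaHy (4.40 and 4.04) lie above those of the other lines, and the dotted line marks a gene listed at 0.

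The main question of the study was which GPCRs the 3 binding lines share and HEK293 lacks. Of 356 GPCR genes in the file, 14 reached 0.5 FPKM in all 6 libraries of the binding lines. HEK293 also reached 0.5 FPKM in both libraries for 12 of these 14, which left CCRL2 and HRH1. The limit was applied to the values as deposited and was not tried after scaling between libraries. The housekeeping list had a median log2(FPKM + 0.5) of 4.49 in PC3M replicate 2 and 5.47 to 7.05 in the other libraries. The same limit may therefore have been stricter in PC3M replicate 2, and receptors may have been left out by it. CCRL2, an atypical chemokine receptor that binds chemerin, was listed at 3.03 and 1.94 FPKM in U937, 2.11 and 2.81 in EaHy, 1.78 and 1.15 in PC3M, and 0.0975 and 0 in HEK293. Its log2 fold changes of 2.42 ± 0.46, 2.43 ± 0.46 and 1.83 ± 0.46 (SE, n = 2 libraries per line) passed the limma test in the 3 lines (adjusted p = 0.009, 0.01 and 0.026). HRH1, the histamine H1 receptor, was listed at 1.05 and 1.71 FPKM in U937, 9.14 and 10.5 in EaHy, 2.46 and 1.22 in PC3M, and 0.214 and 0.25 in HEK293. It rose by 3.82 ± 0.51 in EaHy (limma adjusted p = 0.0022) and 1.62 ± 0.51 in PC3M (adjusted p = 0.047), and in U937 its change of 1.34 ± 0.51 did not pass (adjusted p = 0.15). Over the alternatives the U937 value ranged from 0.047 to 1, and it passed in 1 of them, the fit with only the 2 lines compared (0.047), in which HRH1 also passed in EaHy and PC3M (0.014 and 0.046). The CCRL2 calls were lost without HEK293 replicate 1 or 2, fits that leave a single HEK293 library, but its fold changes moved little. They were 2.55, 2.55 and 1.96 in U937, EaHy and PC3M without HEK293 replicate 1. Without HEK293 replicate 2 they were 2.29, 2.30 and 1.70. CCRL2 also missed the threshold in PC3M without PC3M replicate 2 (0.066) and in U937 without U937 replicate 1 (0.063). The PC3M call of HRH1 was lost without replicate 1 or 2 of PC3M (0.083 and 0.067), of U937 (0.076 and 0.081) or of HEK293 (0.21 and 0.25). Over all alternatives the adjusted p of CCRL2 ranged from 0.006 to 0.13 in U937, 0.0055 to 0.14 in EaHy and 0.012 to 0.52 in PC3M, and that of HRH1 in PC3M from 0.0062 to 0.61. The fold changes of CCRL2 depended on the pseudocount, at 4.17, 4.17 and 3.45 with 0.1 and 1.72, 1.72 and 1.22 with 1. The PC3M call of HRH1 was also lost with a replicate block (limma adjusted p = 0.063), a pseudocount of 1 (0.062) or no filter (0.089).

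Other receptors came close to the presence rule. PTGER4, the EP4 receptor of prostaglandin E2, rose by 4.15 ± 0.56 in U937 and 4.19 ± 0.56 in EaHy (limma adjusted p = 0.0019 and 0.0022), but stood at 0.979 and 0.222 FPKM in PC3M. LPAR6, a lysophosphatidic acid receptor, was at 2.23 and 3.05 FPKM in EaHy, 3.6 and 1.19 in PC3M, 0.928 and 0.0942 in U937, and 0.393 and 0.0313 in HEK293. These 2 joined CCRL2 and HRH1 when the means of the 2 libraries were judged, a total of 4 receptors. With a single library per binding line enough, an alternative chosen after the data were seen, further receptors joined, PTGER2 and GPR132 among them, for a total of 7. In the other direction, 94 GPCRs were present in both HEK293 libraries. Of these, 10 were under 0.5 FPKM in all 6 binding libraries, among them AGTR1, the angiotensin II type 1 receptor, NPY1R, a neuropeptide Y receptor, and ADRA2C, an alpha-2 adrenergic receptor. The number of GPCRs at 0.5 FPKM or more was 115 and 90 in U937, 112 and 61 in EaHy, 70 and 47 in PC3M, and 105 and 103 in HEK293.

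GPR132 varied between replicates, most of all in PC3M. GPR132, a receptor for fatty acid derivatives, was listed at 1.82 and 3.81 FPKM in U937, 0.59 and 0.131 in EaHy, 0 and 6.42 in PC3M, and 0.176 and 0.146 in HEK293. Its log2 fold changes of 2.26 ± 1.05 in U937, 0.33 ± 1.05 in EaHy and 1.49 ± 1.05 in PC3M did not pass the limma test (adjusted p = 0.25, 0.86 and 0.29). The 2 PC3M libraries set this spread. The U937 difference passed without PC3M replicate 1 (adjusted p = 0.027) or replicate 2 (0.025), within a range of 0.019 to 0.73 over all alternatives. The PC3M value was 3.39 (adjusted p = 0.015) without PC3M replicate 1 and −0.40 (0.68) without PC3M replicate 2. GPR65 stood at 0.637 and 0.953 FPKM in U937 and at 0.399 and 0.466 in HEK293, and its log2 fold changes of 0.46 ± 0.43, −0.30 ± 0.43 and −0.31 ± 0.43 in U937, EaHy and PC3M did not pass (limma adjusted p = 0.68, 0.67 and 0.6). GPR4 reached 0.5 FPKM in 1 library, EaHy replicate 1 (1.94), and was not tested.

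**Figure D3:**
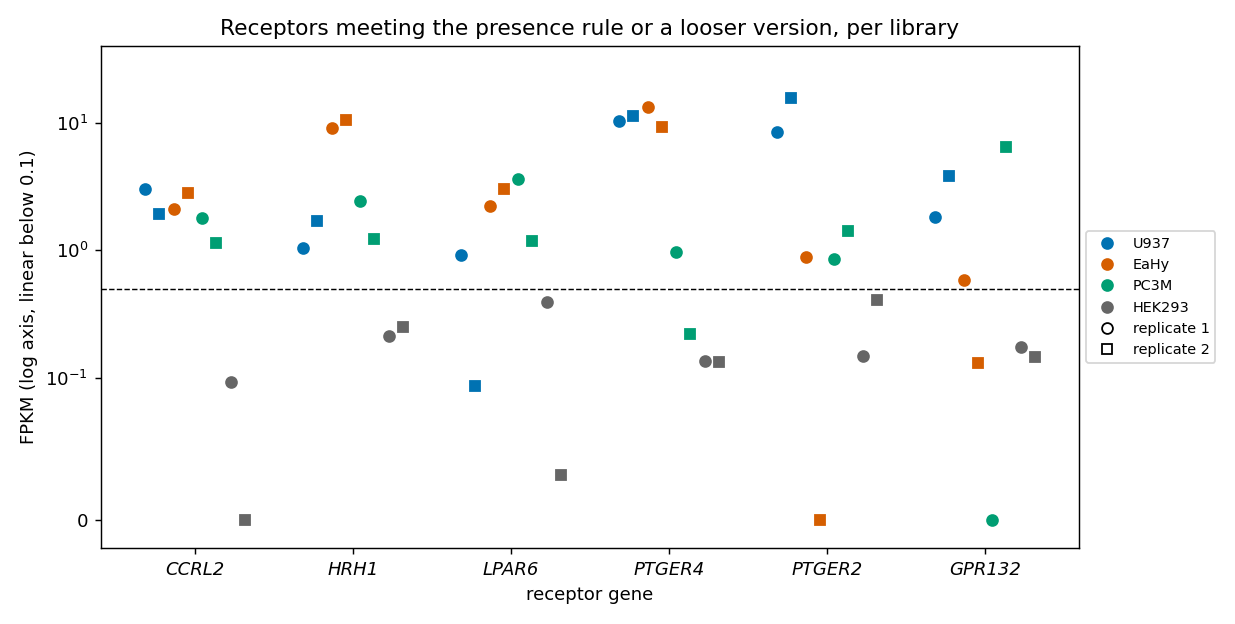
FPKM of 6 GPCR genes (vertical axis, logarithmic above 0.1 and linear below) in each of the 8 libraries, with circles for replicate 1, squares for replicate 2 and colors for the lines. The dashed line marks 0.5 FPKM, and GPR132 lies at 0 in PC3M replicate 1 and at 6.42 FPKM in PC3M replicate 2.

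U937 carried a myeloid transcriptome that HEK293 lacked, while many neuronal and HOX genes and some matrix genes were lower in U937. Of the 49 tested genes of the monocyte and myeloid list, 45 rose against HEK293 (48 adjusted over the list alone, limma camera adjusted p = 8.09e-48, adjusted p = 0.453 with an estimated correlation). CTSG and ELANE, serine proteases of neutrophil granules, rose by 9.69 ± 1.21 and 9.02 ± 1.03 on the log2 scale (SE, n = 2 libraries per line, limma adjusted p = 0.0015 and 0.0011). SRGN, a granule proteoglycan, rose by 9.53 ± 0.89 (adjusted p = 0.00062) and LAPTM5, a lysosomal membrane protein of blood cells, by 8.46 ± 0.77. The other 4 genes with the largest increases, PRTN3, RNASE2, LCP1 and ARHGDIB, rose by 8.06 to 8.89. At the other end, IRS4, an insulin receptor substrate, fell by 8.34 ± 0.59 (adjusted p = 0.00045), PLS3, an actin bundling protein, fell by 8.46 ± 0.83, and CKB, the brain creatine kinase, fell by 7.96 ± 0.78. In all, 728 genes were higher and 1734 lower in U937 than in HEK293 at a limma adjusted p under 0.05. These counts were 896 and 1705 with upper-quartile scaling and 1248 and 1573 with quantile normalization.

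Transcription factors of blood cells were part of this pattern. Of 27 tested genes of blood stem and progenitor cells, 12 rose and 5 fell (13 and 6 adjusted over the list alone, camera adjusted p = 0.000121, adjusted p = 0.68 with an estimated correlation). LYL1, SPI1 and IKZF1 rose by 7.08 ± 0.63, 6.67 ± 0.91 and 5.88 ± 0.44, and KIT, a receptor of progenitor cells, fell by 2.36 ± 0.38. Of 37 interferon-stimulated genes, 11 rose (14 adjusted over the list alone, camera adjusted p = 2.16e-11, adjusted p = 0.523 with an estimated correlation), led by MX2 (6.13 ± 0.45) and BST2 (5.89 ± 0.64). Of 30 NF-κB and inflammatory genes, 5 rose (7 adjusted over the list alone, camera adjusted p = 0.00176, adjusted p = 0.831 with an estimated correlation). SERPINB2 rose by 7.25 ± 0.98, and the chemokine CCL2 was listed at 2.15 and 39.2 FPKM in U937 and at 0 in both HEK293 libraries. Of 8 lymphoid genes, NKG7, BLNK and BANK1 rose (4 adjusted over the list alone, camera adjusted p = 0.00927, adjusted p = 0.773 with an estimated correlation). BANK1 was listed at 1.35 and 0.667 FPKM in U937 and at 0 in both HEK293 libraries. Of 26 integrin and adhesion genes, 5 rose and 6 fell (6 and 8 adjusted over the list alone; 7 and 5 with quantile normalization), with ITGB2, the beta chain of leukocyte integrins, higher by 7.55 ± 0.59 and ALCAM lower at −4.82 ± 0.68. Without U937 replicate 2, HEK293 replicate 1 or HEK293 replicate 2, 7 progenitor genes rose in each case, 2 NF-κB genes rose in each case, and 2, 3 and 2 integrin genes rose, while for the lymphoid list 0 passed in limma without HEK293 replicate 1 (4 at an unadjusted p under 0.05) and 1 without HEK293 replicate 2. The interferon-stimulated calls were 5 without U937 replicate 1, 7 without U937 replicate 2, 2 without HEK293 replicate 1 and 3 without HEK293 replicate 2. The calls of CCL2 (adjusted p = 0.13 and 0.14), BANK1 (0.098 and 0.1) and NKG7 (0.097 and 0.083) were lost without HEK293 replicate 1 or 2, that of BLNK without HEK293 replicate 1 (0.066), that of BANK1 also without U937 replicate 1 (0.068), and that of CCL2 also without U937 replicate 2 (0.089) or PC3M replicate 1 or 2 (0.06 and 0.061).

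Receptors and enzymes of lipid mediators also differed in U937. Of 29 tested GPCRs for lipids and oxylipins, 7 rose and 2 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.00238, adjusted p = 0.773 with an estimated correlation). CYSLTR1, a receptor of cysteinyl leukotrienes, rose by 4.74 ± 0.36, S1PR4, a sphingosine-1-phosphate receptor, by 4.69 ± 0.64, and PTGER2, the EP2 receptor of prostaglandin E2, by 3.98 ± 0.62. LPAR3, a lysophosphatidic acid receptor, fell by 3.77 ± 0.50. Among all 155 tested GPCRs, 26 rose and 30 fell (28 and 40 adjusted over the list alone), and the balance turned to 28 against 25 after quantile normalization. SUCNR1, the succinate receptor, was listed at 14.1 and 19.8 FPKM in U937 and at 0 in both HEK293 libraries. Of 32 genes of arachidonate and EET metabolism, 3 rose and 3 fell (4 and 4 adjusted over the list alone). ALOX5AP, the activating protein of 5-lipoxygenase, rose by 6.99 ± 0.54, PTGS1, cyclooxygenase-1, by 3.70 ± 0.56, and EPHX2, the soluble epoxide hydrolase that converts EETs to diols, fell by 3.51 ± 0.59. Of 58 G protein signalling genes, 5 rose and 6 fell (7 and 12 adjusted over the list alone, 8 and 6 with upper-quartile scaling), with GNA15, a G alpha subunit of blood cells, higher by 4.98 ± 0.52 and GNAZ lower at −3.40 ± 0.47. Camera at the preset correlation did not call the arachidonate, all GPCR and G protein lists in U937 (adjusted p = 0.665, 0.478 and 0.486). For scale, 728 of all 16295 tested genes rose and 1734 fell. Among all GPCRs, 19 rose and 11 fell without U937 replicate 2, 11 and 16 without HEK293 replicate 1, and 12 and 11 without HEK293 replicate 2. Of the G protein genes, 5 rose and 2 fell without U937 replicate 1, 4 and 1 without U937 replicate 2, and 4 and 2 without HEK293 replicate 1 or 2. The EPHX2 call was lost without U937 replicate 2 (adjusted p = 0.058, range over the alternatives 0.0014 to 0.058).

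Genes of the embryonic kidney line were among those that fell in U937. Of 27 neuronal and embryonic kidney genes, 17 fell (22 adjusted over the list alone, camera adjusted p = 4.17e-12, adjusted p = 0.604 with an estimated correlation). UCHL1, a neuronal ubiquitin hydrolase, fell by 7.54 ± 0.86 and NEFM, a neurofilament chain, fell by 6.80 ± 0.48. Of 36 HOX genes, 20 fell (21 adjusted over the list alone, camera adjusted p = 2.88e-11, adjusted p = 0.68 with an estimated correlation), led by HOXB9 (fell by 7.19 ± 0.50). Of 32 matrix genes, 12 fell and 1 rose (15 and 1 adjusted over the list alone, camera adjusted p = 0.000426, adjusted p = 0.85 with an estimated correlation), and of 32 epithelial genes, 10 fell (11 adjusted over the list alone, camera adjusted p = 0.0233, adjusted p = 0.987 with an estimated correlation). CDH2, N-cadherin, fell by 5.29 ± 0.77 and SPINT2, an epithelial protease inhibitor, fell by 5.77 ± 0.82. Without U937 replicate 2, 13 HOX, 11 neuronal, 5 matrix and 5 epithelial genes fell, and without HEK293 replicate 1 or 2, 7 and 6 matrix, 6 and 5 epithelial genes fell. Smaller splits were found for endothelial genes (4 rose and 3 fell of 33), prostate genes (2 and 2 of 10), immediate early genes (3 and 2 of 28) and hypoxia genes (4 fell of 33). B2M and NLRC5 rose among the 4 testable MHC genes (3.38 ± 0.81 and 2.17 ± 0.43), B2M being also the 1 housekeeping gene that rose of 29. HSD17B7 fell among 24 cholesterol synthesis genes and HOTAIR among 10 abundant noncoding RNAs. With limma, 0 genes passed among 12 fatty acid nuclear receptors and binding proteins, 30 stress genes, 40 proliferation genes, 73 ribosomal protein genes and 41 histone genes, with 3, 5, 1, 1 and 0 of these at an unadjusted p under 0.05. The B2M and HSD17B7 calls were lost without replicate 1 or 2 of U937 (adjusted p = 0.082 and 0.14, 0.062 and 0.12) or of HEK293 (0.18 and 0.14, 0.087 and 0.14), and that of NLRC5 without U937 replicate 2 (0.074) or HEK293 replicate 1 or 2 (0.091 and 0.14).

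Of the U937 lists given above as called by camera at the preset correlation, fry also called the myeloid, progenitor, interferon-stimulated, neuronal and HOX lists. It did not call the NF-κB (adjusted p = 0.347), lymphoid (0.144), lipid GPCR (0.189), matrix (0.12) and epithelial (0.189) lists. The number of U937 calls, 2462, was 1612 without U937 replicate 1, 1297 without U937 replicate 2, 1339 without HEK293 replicate 1 and 1164 without HEK293 replicate 2. Without these libraries, in the same order, 25, 42, 39 and 41 of 134 named calls were lost.

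EaHy was set apart from HEK293 by endothelial genes, with some adhesion, matrix, inflammatory and interferon-stimulated genes higher and many HOX and neuronal genes lower. Of 33 tested endothelial genes, 27 rose (30 adjusted over the list alone), and the camera call held with both correlations (adjusted p = 1.72e-38, adjusted p = 0.04 with an estimated correlation). ECSCR, ICAM2, CLEC14A and CDH5, surface proteins of endothelial cells, rose by 8.73 ± 0.72, 7.89 ± 0.59, 7.67 ± 0.68 and 7.47 ± 0.48 (limma adjusted p = 0.00064, 0.00063, 0.00074 and 0.00061). S100A6, a calcium-binding protein, rose by 9.88 ± 0.96 (adjusted p = 0.00088), TM4SF1 by 9.28 ± 0.71, THBS1, a matrix glycoprotein, by 8.93 ± 0.70, and KRT7, a simple epithelial keratin, by 8.80 ± 0.85. In all, 742 genes were higher and 1597 lower in EaHy than in HEK293 at a limma adjusted p under 0.05, against 1151 and 1409 with upper-quartile scaling and 1426 and 1414 with quantile normalization.

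Matrix and adhesion genes were among those that rose in EaHy. Of 32 matrix genes, 13 rose and 4 fell (14 and 5 adjusted over the list alone, camera adjusted p = 4.16e-09, adjusted p = 0.68 with an estimated correlation). COL8A1, a collagen of the endothelium, rose by 7.03 ± 0.50. Of 26 integrin and adhesion genes, 10 rose and 4 fell (15 and 4 adjusted over the list alone, camera adjusted p = 3.11e-09, adjusted p = 0.523 with an estimated correlation), with CD44 higher by 6.79 ± 0.88 and ITGA3 and ITGB3 by 5.34 ± 0.69 and 5.31 ± 0.43. Of 30 NF-κB and inflammatory genes, 13 rose (13 adjusted over the list alone, camera adjusted p = 4.37e-10, adjusted p = 0.604 with an estimated correlation). MMP1, a collagenase, rose by 8.37 ± 0.67 and PLAU, urokinase, by 5.63 ± 0.92. Of 37 interferon-stimulated genes, 14 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 6.24e-15, adjusted p = 0.523 with an estimated correlation), with IFI27 higher by 5.82 ± 0.75 and TRIM22 by 5.26 ± 0.48. Of 27 blood progenitor genes, 7 rose and 4 fell (8 and 6 adjusted over the list alone, camera adjusted p = 0.00927, adjusted p = 0.773 with an estimated correlation, list median −0.10). ERG and FLI1, which endothelial cells also use, rose by 5.38 ± 0.47 and 4.57 ± 0.51. Without HEK293 replicate 1 or 2, 5 NF-κB genes rose in each case, 6 and 5 interferon-stimulated and 6 and 5 integrin genes rose, 4 and 3 progenitor genes rose, and 8 matrix genes rose without HEK293 replicate 2. The NF-κB calls were 8 without EaHy replicate 1, and the progenitor increases 5 without EaHy replicate 2.

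HOX genes and neuronal and embryonic kidney genes were among those that fell in EaHy. Of 36 HOX genes, 26 fell (31 adjusted over the list alone, camera adjusted p = 2.88e-11, adjusted p = 0.68 with an estimated correlation), and of 27 neuronal and embryonic kidney genes, 15 fell and 1 rose (19 and 2 adjusted over the list alone, camera adjusted p = 4.31e-05, adjusted p = 0.773 with an estimated correlation). HOXB9 fell by 7.19 ± 0.50 and ZIC2, a neural transcription factor, fell by 5.59 ± 0.51, while DPYSL3 rose by 5.54 ± 0.78. CKB, PRDX2, IRS4 and CA2 had log2 fold changes of −8.67 ± 0.78, −8.66 ± 0.84, −8.41 ± 0.59 and −7.96 ± 0.63, and CDKN2A, which encodes the p16 cell cycle inhibitor, fell by 6.99 ± 0.89. Of 32 epithelial genes, 8 rose and 6 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.0418, adjusted p = 0.997 with an estimated correlation, list median −0.03), with the desmosomal gene DSG2 lower at −6.21 ± 0.74. The HOX calls were 15 without EaHy replicate 2, 14 without HEK293 replicate 1 and 13 without HEK293 replicate 2, and 4 epithelial genes rose and 4 fell without HEK293 replicate 1, 2 and 4 without HEK293 replicate 2. Of 30 stress genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone), with PHGDH, a serine synthesis enzyme, at −4.59 ± 0.82, and without EaHy replicate 2 or HEK293 replicate 2, 0 passed in limma, with 1 higher and 7 lower, and 1 higher and 6 lower, at an unadjusted p under 0.05. The PHGDH call was lost without EaHy replicate 2 (adjusted p = 0.055) or HEK293 replicate 2 (0.076).

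Several lipid receptors and enzymes differed in EaHy. S1PR1, an endothelial sphingosine-1-phosphate receptor, rose by 5.10 ± 0.48 (limma adjusted p = 0.00087), and LPAR3, lower in U937 too, fell (adjusted p = 0.002). Of 29 lipid and oxylipin GPCRs, 3 rose and 1 fell (5 and 2 adjusted over the list alone), and of all 155 GPCRs, 15 rose and 22 fell (22 and 31 adjusted over the list alone). That balance turned to 25 against 21 with upper-quartile scaling and 26 against 20 with quantile normalization. SUCNR1 was listed at 14.1 and 12.3 FPKM in EaHy and at 0 in both HEK293 libraries. Of 32 arachidonate and EET genes, 3 rose and 4 fell (3 and 6 adjusted over the list alone, 3 and 1 with quantile normalization). GGT5, an enzyme of leukotriene turnover, rose by 4.52 ± 0.45 and PTGS1 by 4.28 ± 0.56, whereas PLA2G4A, cytosolic phospholipase A2, fell by 3.05 ± 0.58 and EPHX2 fell by 2.76 ± 0.59. Of 12 fatty acid nuclear receptors and binding proteins, 2 rose and 2 fell (2 and 3 adjusted over the list alone). PPARG fell by 4.40 ± 0.59, and FABP4, the adipocyte fatty acid binding protein, was listed at 5.57 and 11.4 FPKM in EaHy and at 0 in both HEK293 libraries. Of 58 G protein signalling genes, 6 rose and 8 fell (6 and 11 adjusted over the list alone, 9 and 8 with upper-quartile scaling), with the regulators RGS4 higher by 6.99 ± 0.65 and RGS16 lower at −4.04 ± 0.63. Camera at the preset correlation did not call the arachidonate, all GPCR and G protein lists in EaHy (adjusted p = 0.706, 0.203 and 0.198). It also did not call the lipid GPCR and fatty acid receptor lists (0.0502 and 0.545). For scale, 742 of all 16295 tested genes rose and 1597 fell. Among all GPCRs, 5 rose and 13 fell without HEK293 replicate 1, and 5 and 9 without HEK293 replicate 2. Without EaHy replicate 2, HEK293 replicate 1 or HEK293 replicate 2, 2 arachidonate genes rose and 1, 1 and 0 fell. The calls of FABP4 (adjusted p = 0.056 and 0.06), PLA2G4A (0.074 and 0.11) and EPHX2 (0.066 and 0.12) were lost without HEK293 replicate 1 or 2, and that of EPHX2 also without EaHy replicate 2 (0.078).

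Among the remaining lists, 6 of 49 myeloid genes rose and 2 fell in EaHy (7 and 2 adjusted over the list alone, camera adjusted p = 0.0121, adjusted p = 0.987 with an estimated correlation, list median −0.06). SRGN rose by 7.28 ± 0.89 and CSF2RB, a cytokine receptor chain, by 3.54 ± 0.47. The myeloid increases were 5 without EaHy replicate 2, 3 without HEK293 replicate 1 and 2 without HEK293 replicate 2. Immediate early genes split 3 to 3 of 28 (camera adjusted p = 0.00519, adjusted p = 0.897 with an estimated correlation), and 8 rose and 1 fell after upper-quartile scaling. NLRC5 and CD74 rose among 4 MHC genes, 3 of 33 hypoxia genes fell, 2 of 10 prostate genes rose and 2 fell, NCAM1 fell among 8 lymphoid genes, and the noncoding RNA MEG3 rose and HOTAIR fell. The 41 histone genes had a list median of 3.02 (camera adjusted p = 3.74e-12, adjusted p = 0.773 with an estimated correlation), with EaHy replicate 2 far above EaHy replicate 1. With limma, 0 of the histone genes passed, with 10 at an unadjusted p under 0.05, and 33 passed without EaHy replicate 1. Likewise 0 passed among 24 cholesterol synthesis, 40 proliferation, 73 ribosomal protein and 29 housekeeping genes, with 1, 3, 4 and 4 at an unadjusted p under 0.05. The calls of NLRC5 (adjusted p = 0.066 and 0.1) and CD74 (0.14 and 0.13) were lost without HEK293 replicate 1 or 2, and that of CD74 also without EaHy replicate 2 (0.065).

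Of the EaHy lists given above as called by camera at the preset correlation, fry also called the endothelial, integrin, interferon-stimulated, neuronal and HOX lists. It did not call the matrix (adjusted p = 0.109), NF-κB (0.135), progenitor (0.242), histone (0.416), immediate early (0.689), myeloid (0.849) and epithelial (0.9) lists. The number of EaHy calls, 2339, was 1099 without HEK293 replicate 1 and 965 without HEK293 replicate 2, and 1633 (756 higher, 877 lower) without the histone-rich EaHy replicate 2. Without these libraries, in the same order, 47, 54 and 27 of 137 named calls were lost.

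PC3M differed from HEK293 by histone genes and some epithelial and inflammatory genes on the higher side and by HOX and neuronal genes on the lower side, with far more genes lower than higher in the values as deposited. Of 32 tested epithelial genes, 11 rose and 6 fell (12 and 6 adjusted over the list alone, camera adjusted p = 5.01e-09, adjusted p = 0.68 with an estimated correlation, list median 0.08). KRT19, an epithelial keratin, was listed at 177 and 57.8 FPKM in PC3M and at 0 in both HEK293 libraries. SFN, a stratified epithelium 14-3-3 protein, rose by 6.72 ± 0.50 (limma adjusted p = 0.00086) and CLDN4, a tight junction claudin, by 5.04 ± 0.75 (adjusted p = 0.0043), while the junction gene JUP fell by 4.50 ± 0.61. The epithelial list gave 8 increases and 2 decreases without PC3M replicate 2, 4 and 2 without HEK293 replicate 1, and 5 and 1 without HEK293 replicate 2. S100A6 rose by 9.67 ± 0.96 (adjusted p = 0.0013). In all, 390 genes were higher and 4127 lower in PC3M than in HEK293, and the median fold change of all tested genes was −1.26, against −0.22 in U937 and −0.67 in EaHy. Upper-quartile scaling moved these medians to −0.29, −0.10 and −0.24 in PC3M, U937 and EaHy, and then 1134 genes were higher and 1973 lower in PC3M. With quantile normalization 1283 were higher and 1463 lower. Camera ranks a list against the other tested genes. With a median of −1.26 over all tested genes as deposited, a list with a median near 0 can be called upward.

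Histone genes were the group with the largest change in PC3M. Of 41 tested replication histone genes, 32 rose (37 adjusted over the list alone, camera adjusted p = 2.48e-44, adjusted p = 0.523 with an estimated correlation), with a list median of 7.17. HIST1H2AE rose by 10.50 ± 1.63 (limma adjusted p = 0.0051), from 0 and 0.252 FPKM in HEK293 to 1160 and 675 FPKM in PC3M. It stood at 2.07 FPKM in EaHy replicate 1 and at 186 FPKM in EaHy replicate 2. HIST1H4K and HIST1H4J, near-identical genes of histone H4, rose by 9.43 ± 2.15 and 9.39 ± 2.15. RMRP, which is not polyadenylated, rose by 11.17 ± 2.96 (adjusted p = 0.03). Without PC3M replicate 1, 11 histone genes passed, and without PC3M replicate 2, 0 passed in limma with 34 at an unadjusted p under 0.05. Without HEK293 replicate 1, 7 passed, and without HEK293 replicate 2, 1 passed. The calls of HIST1H4K and HIST1H4J were lost without PC3M replicate 2 (adjusted p = 0.1 and 0.11), HEK293 replicate 1 (0.08 and 0.081) or HEK293 replicate 2 (0.1 each), and that of RMRP without replicate 1 or 2 of PC3M (0.069 and 0.15) or of HEK293 (0.064 and 0.18).

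Some inflammatory and interferon-stimulated genes rose in PC3M. Of 30 NF-κB and inflammatory genes, 6 rose (4 adjusted over the list alone, camera adjusted p = 3.12e-10, adjusted p = 0.604 with an estimated correlation, list median 0.35), among them PLAU (5.28 ± 0.92), the chemokine CXCL1 (4.65 ± 0.71) and IL8 (4.53 ± 1.03). Of 37 interferon-stimulated genes, 4 rose (4 adjusted over the list alone, camera adjusted p = 6.75e-09, adjusted p = 0.545 with an estimated correlation, list median 0.28), with IFI44 higher by 4.71 ± 0.53 and ISG15, a ubiquitin-like modifier, by 5.16 ± 0.88. Of 26 integrin and adhesion genes, 4 rose and 6 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.0229, adjusted p = 0.773 with an estimated correlation, list median −0.24), which became 6 and 5 with upper-quartile scaling. ITGA3 rose by 3.53 ± 0.69 and MCAM fell by 3.64 ± 0.53. CDH11, a mesenchymal cadherin, rose by 5.42 ± 0.79, whereas 12 of the 32 matrix genes fell and 1 rose (13 and 3 adjusted over the list alone), with FN1, fibronectin, at −3.75 ± 0.63. CA9, a carbonic anhydrase induced by hypoxia, rose by 5.35 ± 0.52, while in its list 2 rose and 5 fell of 33 hypoxia genes (2 and 1 with upper-quartile scaling) and 1 rose and 1 fell of 24 cholesterol synthesis genes. Without HEK293 replicate 1 or 2, 2 and 1 NF-κB and 2 and 1 interferon-stimulated genes rose and 3 matrix genes fell, and 6 interferon-stimulated genes rose without PC3M replicate 2. Without PC3M replicate 1, 16 hypoxia genes fell and 1 rose. The calls of ITGA3 (adjusted p = 0.089 and 0.081) and IL8 (0.094 and 0.11) were lost without HEK293 replicate 1 or 2, that of FN1 without HEK293 replicate 1 (0.072), those of PLAU, ISG15 and MCAM without HEK293 replicate 2 (0.072, 0.056 and 0.063), and that of IL8 also without PC3M replicate 1 or 2 (0.052 and 0.072).

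On the lower side, 32 of 36 HOX genes fell in PC3M (33 adjusted over the list alone, camera adjusted p = 1.19e-10, adjusted p = 0.68 with an estimated correlation), with HOXB9 at −6.90 ± 0.50 and HOXA5 at −5.65 ± 0.61. Of 27 neuronal and embryonic kidney genes, 17 fell and 1 rose (18 and 1 adjusted over the list alone, camera adjusted p = 0.00129, adjusted p = 0.85 with an estimated correlation), with NEFM at −7.07 ± 0.48. IRS4 fell by 8.91 ± 0.59, AMOT, a scaffold of tight junctions, fell by 8.16 ± 0.53, AKR1B1, aldose reductase, fell by 7.93 ± 0.66, and TSC22D3, a glucocorticoid-induced gene, fell by 7.63 ± 0.85. VTRNA1-3, a vault RNA, fell by 7.39 ± 0.98, and the pseudogenes NACAP1 and HNRNPA1P33 had changes of −7.34 ± 1.62 and −7.10 ± 1.67. Of 40 proliferation genes, 8 fell (7 adjusted over the list alone), with MKI67 at −4.57 ± 1.18, and of 30 stress genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone). Of 27 blood progenitor genes, 8 fell (8 adjusted over the list alone), and of 29 housekeeping genes, 5 fell (5 adjusted over the list alone), with POLR2A at −4.08 ± 0.93. Among all 16295 tested genes, 4127 fell, so decreases of a like share do not set a list apart. Camera at the preset correlation did not call the proliferation, stress, progenitor and housekeeping lists (adjusted p = 0.182, 0.837, 0.945 and 0.705). Of 73 ribosomal protein genes, RPLP1 and RPS2 fell (camera adjusted p = 0.000363 for a higher rank than other genes, adjusted p = 0.987 with an estimated correlation, list median −0.27), and 3 rose instead with upper-quartile scaling. Without PC3M replicate 2, HEK293 replicate 1 or HEK293 replicate 2, 19, 21 and 19 HOX genes fell, and of the proliferation and housekeeping genes 0 passed in limma, with 5, 11 and 5 and 6, 7 and 5 at an unadjusted p under 0.05. Without PC3M replicate 1, 26 proliferation, 14 stress and 12 housekeeping genes fell. The calls of NACAP1, HNRNPA1P33, MKI67, POLR2A, RPLP1 and RPS2 were lost without PC3M replicate 2 (adjusted p = 0.096 to 0.18), HEK293 replicate 1 (0.078 to 0.14) or HEK293 replicate 2 (0.098 to 0.25), that of RPS2 also without U937 replicate 1 or 2 (0.062 and 0.068), and that of MKI67 also without U937 replicate 1 (0.05).

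For lipid signalling, 1 of 29 lipid and oxylipin GPCRs rose and 2 fell in PC3M (1 and 0 adjusted over the list alone, camera adjusted p = 0.00376 upward, adjusted p = 0.773 with an estimated correlation, list median −0.19), and 3 rose and 0 fell with upper-quartile scaling. LPAR1, a lysophosphatidic acid receptor, rose by 3.28 ± 0.66, and TBXA2R, the thromboxane receptor, fell by 1.88 ± 0.53. Of all 155 GPCRs, 7 rose and 31 fell (6 and 28 adjusted over the list alone), but 17 rose and 14 fell with upper-quartile scaling and 25 rose and 9 fell with quantile normalization. SMO, the hedgehog pathway receptor, fell by 4.23 ± 0.58. Of 12 fatty acid nuclear receptors and binding proteins, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.00787, adjusted p = 0.68 with an estimated correlation, list median −0.20). PPARG rose by 2.18 ± 0.59 and PPARA fell by 2.57 ± 0.48. Of 32 arachidonate and EET genes, 2 rose and 6 fell (2 and 6 adjusted over the list alone), which became 6 and 1 with upper-quartile scaling. EPHX2 fell by 2.26 ± 0.59 and EPHX1, the microsomal epoxide hydrolase, fell by 4.14 ± 0.98, and TBXAS1, thromboxane synthase, rose by 2.62 ± 0.76. Of 58 G protein signalling genes, 2 rose and 16 fell (2 and 18 adjusted over the list alone), and 6 rose and 8 fell with upper-quartile scaling. Among all 16295 tested genes, 390 rose and 4127 fell in the values as deposited. Camera at the preset correlation called neither the list of all GPCRs nor the G protein list (adjusted p = 0.0836 and 0.945). In the other lists, 1 of 49 myeloid genes rose and 5 fell (camera adjusted p = 0.0136 upward, adjusted p = 0.987 with an estimated correlation, list median −0.44, 3 and 1 with quantile normalization), 1 of 33 endothelial genes rose and 3 fell (camera adjusted p = 0.000708 upward, adjusted p = 0.523 with an estimated correlation, list median −0.04, 4 and 3 with upper-quartile scaling), and 3 of 28 immediate early genes rose and 6 fell (camera adjusted p = 0.0286 upward, adjusted p = 0.987 with an estimated correlation, list median −0.60, 5 and 1 with upper-quartile scaling). Lymphoid and prostate genes each gave 2 decreases, of 8 and 10 genes (2 prostate genes rose and 0 fell with upper-quartile scaling), RMRP rose and HOTAIR fell among 10 noncoding RNAs, and 0 of 4 MHC genes passed in limma, with 0 at an unadjusted p under 0.05. Among all GPCRs, 6 rose and 10 fell without PC3M replicate 2, and 1 rose and 11 fell without HEK293 replicate 1 or 2. The G protein decreases were 28 without PC3M replicate 1, 6 without PC3M replicate 2, 6 without HEK293 replicate 1 and 4 without HEK293 replicate 2. For the arachidonate list 0 passed in limma without HEK293 replicate 1 or 2, with 7 and 9 at an unadjusted p under 0.05. The calls of LPAR1, TBXA2R, PPARG, PPARA, TBXAS1, EPHX1, EPHX2 and RMRP were lost without HEK293 replicate 1 (adjusted p = 0.064 to 0.18) or 2 (0.074 to 0.2). Those of TBXA2R, PPARA, EPHX1, EPHX2 and RMRP were lost without PC3M replicate 2 (0.059 to 0.15), those of TBXA2R, TBXAS1 and RMRP without PC3M replicate 1 (0.05 to 0.091), and those of TBXA2R, PPARG, TBXAS1 and EPHX2 without U937 replicate 1 (0.051 to 0.061) or 2 (0.053 to 0.061).

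Of the PC3M lists given above as called by camera at the preset correlation, fry also called the HOX and neuronal lists. It did not call the histone (adjusted p = 0.178), epithelial (0.347), NF-κB (0.435), interferon-stimulated (0.347), integrin (0.268), endothelial (0.268), myeloid (0.41), immediate early (0.504), ribosomal protein (0.598), lipid GPCR (0.701) and fatty acid receptor and binding protein (0.945) lists. With a term for the 3 histone-rich libraries, an alternative chosen after the data were seen, 0 genes passed in PC3M with limma, with 1938 at an unadjusted p under 0.05, so every PC3M call above was lost. The term rested on the difference between EaHy replicate 2 and EaHy replicate 1 alone. In each other line, both libraries lay on the same side of the split into histone-rich and histone-poor. The term was not measured within PC3M. The median standard error rose from 0.68 to 1.16, and the median fold change of all tested genes went from −1.26 to −0.72. Of the PC3M calls, 99% kept their sign, and the fold changes of all tested genes correlated with the former ones at 0.6. With the term, CA9 stood at 5.78 (limma adjusted p = 0.071) and MKI67 at −0.54 (0.9). The 4517 calls became 7103 without PC3M replicate 1, 1008 without PC3M replicate 2, 890 without HEK293 replicate 1, 745 without HEK293 replicate 2, 2916 without U937 replicate 1 and 2991 without U937 replicate 2, and 18, 65, 80, 97, 31 and 28 of 147 named calls were then lost.

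**Figure D4:**
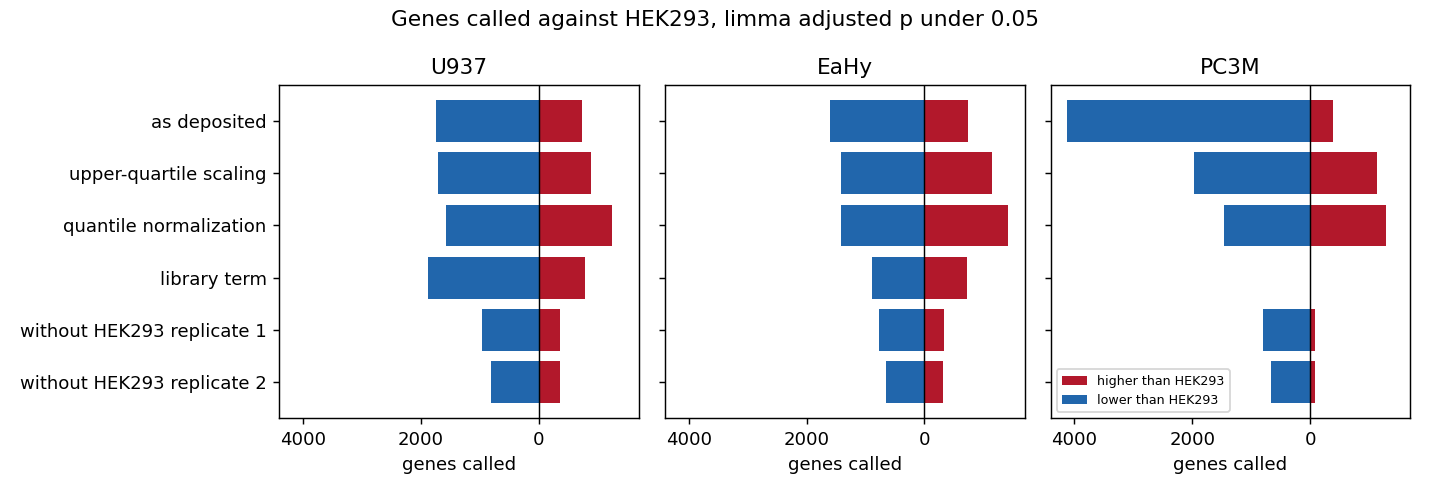
Number of genes called against HEK293 by limma at an adjusted p under 0.05 (horizontal axis, higher to the right and lower to the left) for the 3 binding lines under 6 settings. The bars for PC3M go from 4127 lower and 390 higher as deposited to 0 with the term for the 3 histone-rich libraries.

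Genes that separated all 3 binding lines from HEK293 in the same direction were mostly ones that HEK293 expressed. A total of 819 genes were lower and 38 higher in all 3 lines. IRS4, AMOT, CA2, HOXB9 and NEFM fell by at least 6.78 in each line. IRS4 stood at 260 and 221 FPKM in HEK293 and at no more than 0.595 FPKM elsewhere. CKMT1A and CKMT1B, paired genes of mitochondrial creatine kinase that share sequence, changed by −5.80 to −6.11, and the neuronal gene NRN1 by −5.67 to −6.52. EPHX2 was also lower in all 3 lines, at 5.68 and 7.98 FPKM in HEK293 and 0.00913 to 1.97 FPKM in the others. Its limma adjusted p was 0.0051, 0.017 and 0.029 in U937, EaHy and PC3M, and ranged over the alternatives from 0.0014 to 0.058, 0.0074 to 0.12 and 0.015 to 0.61, with the U937 call lost without U937 replicate 2 (0.058), the EaHy call without EaHy replicate 2 (0.078), and the EaHy and PC3M calls without HEK293 replicate 1 (0.066 and 0.099) or 2 (0.12 and 0.17). The PC3M call was also lost without PC3M replicate 2 (0.14) or U937 replicate 1 or 2 (0.051 and 0.053).

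Among the 38 genes higher in all 3 lines, S100A6 rose by 7.04 ± 0.96, 9.88 ± 0.96 and 9.67 ± 0.96 in U937, EaHy and PC3M. LTBR, the lymphotoxin beta receptor, rose by 5.59 ± 0.92, 5.56 ± 0.92 and 5.35 ± 0.92 (limma adjusted p = 0.0044, 0.0053 and 0.0075), and SLC16A3, a lactate exporter, by 6.67 ± 0.86, 5.35 ± 0.86 and 5.62 ± 0.86. GSDMD and CASP4, an executor and an initiator of pyroptotic cell death, rose by 4.55 to 5.29 and by 3.73 to 7.10. LGALS1, a secreted galectin, rose by 4.15 to 6.34. SNRPN and SNURF, which overlap in a shared transcript, rose by 4.43 to 6.27 and 4.07 to 4.58, and C14orf169 and RIN1 by 4.18 to 5.24 and 3.75 to 4.37. CCRL2 was the 1 GPCR among the 38. The calls of CCRL2, GSDMD and RIN1 were lost without HEK293 replicate 1 or 2 in all 3 lines (adjusted p = 0.052 to 0.21), those of SNRPN and SNURF in PC3M (0.056 to 0.095) and of LGALS1 in U937 (0.075 and 0.099) likewise, and those of LTBR and CASP4 in PC3M without HEK293 replicate 2 (0.057 and 0.072). Without U937 replicate 2, the U937 calls of GSDMD, LGALS1 and RIN1 were lost (0.091, 0.09 and 0.13), without U937 replicate 1 those of CCRL2 and RIN1 (0.063 and 0.075), and without PC3M replicate 2 that of CCRL2 in PC3M (0.066). The 3 contrasts share the 2 HEK293 libraries, so the lists are not independent, and the controls could not be divided between contrasts. Chance overlap of lists of these sizes would give 0.793 higher and 43.04 lower genes if they were independent. Simulated unchanged data with shared controls gave a mean of 0.02 higher and 0 lower in 50 draws. In these draws a mean of only 0.36, 0.28 and 0.34 genes were called in U937, EaHy and PC3M. An overlap near 0 was therefore fixed beforehand. The simulation cannot show how much of the observed overlap the shared HEK293 libraries make. The covariance of the fold changes was 1.14, 0.923 and 1.92 (U937 with EaHy, U937 with PC3M, EaHy with PC3M), against simulated means of 0.353, 0.355 and 0.352. The correlation of the fold changes across genes was 0.417, 0.321 and 0.635 for the same pairs, against simulated means of 0.501, 0.502 and 0.5. The simulation gave all lines the same mean, so its correlations and covariances came from the shared controls by construction. Real differences between lines change both quantities. Neither comparison can therefore show how much change the binding lines share apart from the shared controls. EaHy replicate 2 and both PC3M libraries were the histone-rich ones, which the simulation did not model, and EaHy replicate 2 correlated with PC3M replicate 1 at 0.83, against 0.78 with EaHy replicate 1.

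The 38 and 819 shared genes became 5 and 459 without HEK293 replicate 1, 3 and 404 without HEK293 replicate 2, 17 and 485 without U937 replicate 2, 25 and 604 without U937 replicate 1, and 35 and 440 without PC3M replicate 2, and 86 and 546 with upper-quartile scaling. With the term for the 3 histone-rich libraries, 0 genes were shared in either direction by limma, since 0 passed in PC3M (1938 at an unadjusted p under 0.05). The PC3M fold changes of AMOT, BEX4 and CKMT1A were then −7.35, −5.86 and −5.49 (limma adjusted p = 0.071, 0.077 and 0.071), and that of EPHX2 was −1.61 (0.61).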

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

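The histone-rich library term, the rescaling without small RNA and histone genes, the histone-poor fit and the presence rule for a single library per line were chosen after the result was seen, and the other tests of this part were planned. Unless a cause is named, the cause was not tested.

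Of 418 calls of named genes, 159 held under all alternatives run, and 208 under all except the library term. Under quantile normalization, ADM and ANKRD37 in PC3M reversed, to 1.53 and 1.59 (adjusted p = 0.043 each) from −0.09 and −0.21, which had not passed. Without HEK293 replicate 1 or 2, 166 and 192 named values no longer passed.

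The number of called genes was 2462 in U937, 2339 in EaHy and 4517 in PC3M, with 38 higher and 819 lower in all 3. Leaving out a library gave 1164 to 2702 in U937, 965 to 2986 in EaHy and 745 to 7103 in PC3M, and 3 to 35 higher and 404 to 940 lower in all 3. The lowest values of called genes came without HEK293 replicate 2. Testing for a fold of at least 2, a stricter test, gave 1231, 983 and 849, with 10 and 304 in all 3. Quantile normalization gave 2746 in PC3M, with 134 and 425 in all 3. Upper-quartile scaling gave 86 higher in all 3, the rescaling 67. A pseudocount of 0.1 gave 494 lower in all 3. Without a filter, with more genes tested, 2802 passed in PC3M and 22 were higher in all 3. With the library term, 0 passed in PC3M in limma (1938 at an unadjusted p under 0.05), 0 were higher and 0 lower in all 3, and the median standard error in PC3M went from 0.68 to 1.16, while 99% of its calls kept their sign. This term rested on the difference between the EaHy libraries and was not measured within PC3M.

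Of GPCRs, 2 met the presence rule, 1 at a limit of 0.1 FPKM (CCRL2), 1 with presence at 1 FPKM and absence under 0.1 FPKM, 4 by means, 1 by limma in all 3 comparisons, 7 with a single library per line, and 2 to 3 without 1 library. Camera called 11, 13 and 13 lists in U937, EaHy and PC3M. With an estimated correlation it called 0, 1 (endothelial genes) and 0, and fry, which tests another question, called 5, 5 and 3. The camera totals of U937 and EaHy and the fry total of PC3M each include 1 list whose result is not given. The depth in counts is unknown, so its limit on low values could not be set. The presence rule was run on FPKM as deposited alone and not after scaling.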

Other observations

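The tests below were chosen after the result was seen, except that of YTHDC1. The genes of the next paragraph were chosen after their values were seen.

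IFI16 and MB21D1, DNA sensors, and IL18 and MLKL, genes of inflammatory cell death, were higher in the 3 binding lines than in HEK293. MLKL rose by 3.59 ± 0.88, 4.68 ± 0.88 and 3.56 ± 0.88 in U937, EaHy and PC3M (limma adjusted p = 0.027, 0.0097 and 0.025). MB21D1 was near the threshold in EaHy (2.51 ± 0.70, adjusted p = 0.047). The alternatives were not run for IFI16, MB21D1, IL18 and MLKL one by one. TMEM173 and PYCARD, looked up with these genes, did not pass in PC3M (1.39 ± 0.77 and −0.08 ± 0.58, limma adjusted p = 0.19 and 0.95). ETV4 and ETV5, ETS factors, were higher as well, as were S100A4 and TMSB4X, while SPRY4, looked up with ETV4 and ETV5, did not pass in any of the 3 lines (adjusted p = 0.41, 0.088 and 0.29). CTNNA1, alpha-catenin, stood at 0.0631 and 0.0619 FPKM in PC3M (fell by 6.52 ± 0.58, limma adjusted p = 0.0012). In EaHy, the neighbours of CDKN2A were low too: MTAP stood at 1.25 and 0.255 FPKM (fell by 3.94 ± 0.67) and CDKN2B at 0.139 and 0 FPKM (fell by 2.81 ± 0.55). In PC3M these differences went along with the library difference described above, and no explanation of these values was tested.

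GPR132 was listed at 0 in PC3M replicate 1 and at 6.42 FPKM in PC3M replicate 2. Low depth of PC3M replicate 1 is argued against, since 11 of 1761 genes between 4 and 10 FPKM in replicate 2 (0.625%) were at 0 there, and their median was 15.8 FPKM. Carry-over from U937 would need 169% of the U937 level, against at most 0.392% for 8 myeloid genes high in U937 and under 0.5 FPKM in HEK293 and PC3M replicate 1, and 0 annotated genes lay within 3000 bases. A failed estimate for that gene, or a difference between the cultures, could each remain: 23 genes were at 0 in PC3M replicate 1 and at 3 FPKM or more in replicate 2, among them S1PR3 (0 and 132 FPKM), while RPPH1 was at 0 in PC3M replicate 2 alone. No biological explanation was tested.

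The 42 histone genes were higher in EaHy replicate 2 than in EaHy replicate 1 by a median of 5.91 on the log2 scale. More cells in S phase is argued against by the proliferation list, with a median of −1.10. A bias toward all transcripts of 382 to 2153 bases is argued against by 2017 other protein-coding genes, with a median of −0.21. Their longest annotated transcript lay in that range, but they were not matched to the histones within it. The 74 ribosomal protein genes had a median of 0.48. Over all tested genes, EaHy replicate 1 minus EaHy replicate 2 had a median of 0.5, so a typical gene was lower in replicate 2. The proliferation list was lower than that typical gene. The length-range and ribosomal protein genes were above it, so a weak bias toward shorter transcripts stays open. A bias limited to the shortest transcripts was not tested. More RNA without a poly(A) tail may be the source, since 117 small Cajal body and H/ACA RNAs were higher by a median of 8.23. These RNAs are also small, so their rise cannot separate a missing tail from small size. The labels name the same depletion and library kits for all libraries, so what step differed stays open. Apart from more cells in S phase, no biological explanation was tested.

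Of 183 protein-coding genes at 0 in all 8 libraries, olfactory receptors left out, 169 lay in 4 runs of neighbours, with 118 and 33 genes on chromosome 6, 12 on chromosome 17 and 6 on chromosome 4, and no other run was longer than 2. Absence of expression as the whole source is argued against by 2 lists written beforehand: of 103 ribosomal protein and housekeeping genes, 2 were at 0 in all 8 libraries, RPS18 and TUBB, and both lay in these runs. For the other genes of the runs it was not tested. Unassigned reads of genes carried on several haplotype sequences of the build may be the source. YTHDC1, named beforehand for the region on chromosome 4, had a lowest value of 0 and was at 0 in all 8 libraries. GPCRs in such regions, GABBR1, CRHR1 and MAS1L among them, could therefore not be judged as missing.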
